A study of Glycine max with 2 samples.

How the data were processed

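RNA from mid-maturation seeds of wild-type and SP- soybean was converted to cDNA libraries with a kit for mRNA sequencing, per the labels' protocols, with 1 library per group. The deposited files are lists of read alignments with 8 columns and no header. They hold the deposited read name, strand, reference name, position, read sequence, qualities, number of further places of the read and mismatches. The position, a coordinate that is neither a count nor a score as deposited, was used to place each read. Bowtie 0.9.9.3 is named in the submitters' processing notes. The reference sequence set, the alignment options and the filters are not given in the sources used here. Reference names were those of assembled transcript contigs (59134 of the 97141 sequences with reads had a TC name) and of single cDNA sequences. Every read occurred once with 1 reported place, so reads with several equally good places had already been assigned to 1 of them. Reads for which the files list no further place were taken as single-place reads, 36.4% of the wild-type reads and 31.4% of the SP- reads. How the files count further places is not stated, so such reads may still match elsewhere. A design that divided such reads among their places could not be applied, and reads were counted where the files report them.

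Reads were counted per reference sequence with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. The wild-type library had 10450084 reads and the SP- library 9337799. Each was sequenced in 1 lane of its own in 2 runs, so lane and group cannot be told apart. The runs differed in quality: 85.4% of wild-type reads and 83.6% of SP- reads had no mismatch in the first run, and 65.1% and 62.3% in the second. A share is given with its exact Clopper-Pearson 95% interval. A ratio is given with the exact conditional interval of the SP- over wild-type counts (SciPy 1.17.1), after scaling by the median ratio of sequences with at least 100 reads. The scaling factor was 0.593. For single sequences and list medians, 0.5 was added to each count on the log2 scale. Sequences with at least 20 reads in the 2 libraries together were called higher or lower when the whole interval lay beyond 2-fold. Many reference sequences stand for parts or copies of 1 gene, so their numbers are not numbers of genes. No p-value was computed.

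The files do not pair reference sequences with gene names, and the table of 59048 soybean genes at hand matched 0 of the reference names. Names were therefore assigned by sequence. The covered bases of each reference sequence were rebuilt from the reads and their mismatches, then compared by translated BLAST 2.17.0 with a panel of 78 protein sequences, and with 6 pieces of rRNA. The panel was written from general knowledge and not taken from a database, so a panel sequence can contain errors and a name means similarity to it. The 7 storage globulins matched over their full length with at least 99.4% identity, and some other names rest on weaker matches, such as PR-10 at 80.4% and sucrose synthase at 69.5%. A match needed at least 60% identity over 40 residues, and had to cover 30% of the reference sequence or 100 residues. An rRNA match needed 90% identity and took precedence. Sequences that overlapped a named sequence by at least 100 bases with 95% identity took its name. In all 1733 reference sequences were named, 397 of them by overlap, holding 64.4% of the wild-type reads and 70.1% of the SP- reads.

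The panel was fixed before any ratio was computed. The matching thresholds were settled over 4 passes of the matching step, after ratios had been seen. The passes changed the smallest match length, added the overlap step, the coverage share and the precedence of rRNA, and switched off the filter for simple sequence. The direction of a gene or list was not a criterion. A further 10 families of sequences without a panel match were named by short protein motifs (Biopython 1.88). These motifs were chosen after the ratios were known, 1 of them was narrowed and others were dropped after their matches had been seen, and their results stand only among the closing observations.

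The rule for named genes was set before the data were examined. It takes the storage globulins with at least 20 reads, the 10 sequences with the highest lower bound and the 10 with the lowest upper bound of the ratio among those with at least 100 reads. It also takes the 10 most abundant sequences of each library and up to 4 of the most abundant members of each list. It named 201 sequences, which are described here by family. Sums per protein, and members singled out as exceptions within a family, were added to the rule after the values were seen. The 21 gene lists had been written as patterns on product names. Without product names they were filled through the panel instead, so each list stands for a few proteins, and 2 lists had no measured member. A list's median was placed among 10000 random lists of the same size, matched on mean abundance in 20 bins.

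The size rule and the lists were tested on 2 simulated libraries, in which 200 of 97141 sequences were changed. The first had the wild-type depth and the second 0.6 of it. Both were drawn from the mean abundances over the 2 real libraries, so the real difference in composition was absent. A 3-fold change was called in 52 of 67 sequences (77.6%), an 8-fold change in 65 of 66 (98.5%) and a 1.5-fold change in 0 of 67. Of 34172 unchanged sequences 2 were called. A simulated list of 30 sequences raised by 1.5 on the log2 scale lay at percentile 100 of its matched random lists, and an unchanged list of 30 at percentile 58.0. The simulation held counting error only, so it says nothing about differences between plants or library preparations. Alternatives covered 3 other scalings, other read minimums and size rules, only reads with a single place, only alignments without mismatches, duplicate reads counted once, and each run left out. Leaving out rRNA, leaving out storage globulins and rRNA, and names by protein match alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9.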

Results

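Transcripts of soybean (Glycine max) seeds at mid-maturation were sequenced from greenhouse-grown plants of a wild type and of SP-, a line in which RNA interference was directed against the seed storage proteins. The comparison asks how the transcripts of the maturing seed differ when storage protein synthesis is suppressed. Each group had 1 library, so no spread between replicates could be measured and no test was possible. The difference between the libraries has no replicate check, and every statement below describes these 2 libraries and not the conditions. The wild-type library held 10450084 aligned reads of 36 bases and the SP- library 9337799, and each had been sequenced in 2 runs. Ribosomal RNA took 12.5% of the wild-type reads and 32.3% of the SP- reads. Ratios are SP- over wild type after scaling to the median ratio of the 11661 reference sequences with at least 100 reads. Intervals are exact 95% intervals, and they and the detection floors cover counting error only. A read count of 3, the floor used here, corresponds to 0.287 RPM in the wild-type library and 0.321 RPM in the SP- library. Gene names rest on sequence matches and not on an annotation of the files.

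The targeted storage globulins, the main nitrogen reserve of the seed, took a much smaller part of the SP- library, but only 4 of the 7 globulin genes matched here were lower. Glycinin and β-conglycinin together held 29.1% of the wild-type reads (Clopper-Pearson interval 29.06 to 29.1%) and 11.9% of the SP- reads (11.92 to 11.96%). Glycinin G1 had 720844 reads in the wild type and 5599 in SP-, a ratio 76.3-fold lower in SP- (74.4 to 78.4). Glycinin G2 was 85.6-fold lower (83.0 to 88.2), the α′ subunit of β-conglycinin 95.9-fold lower (92.6 to 99.3) and the α subunit 14.99-fold lower (14.8 to 15.2). Counting duplicates once limits each start position to 1 read per strand. The log2 ratios were then -1.59 for G1, -1.65 for G2, -1.88 for α′ and -1.03 for α.

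Glycinin G5 was 3.67-fold higher in SP- (3.65 to 3.68) and the β subunit of β-conglycinin 2.28-fold higher (2.26 to 2.30) in sum. With single-place reads their log2 ratios were 1.94 and 1.66. With duplicates counted once both lay within 2-fold, at 0.72 and 0.74. That count limits each start position to 1 read per strand, which compresses the ratios of abundant sequences, and rRNA came to 0.73. Of the 10 β subunit sequences 7 were higher and 2 lower, and 1 of the lower ones, at log2 -2.59, held 31565 of the 83214 wild-type reads. That sequence, AW317985, turned to 0.46 with duplicates counted once. Glycinin G4 was 1.69 times its wild-type level (1.68 to 1.69), within the 2-fold size rule. Its log2 ratio of 0.75 turned to -0.15 with scaling to the total outside storage globulins. G5 and the β subunit also fell within 2-fold there, at 0.97 and 0.29. That total still includes rRNA. With the total outside rRNA, G4 had a log2 ratio of 0.53. G5 alone made up 56.1% of the storage globulin reads of SP-, against 9.46% in the wild type. Summed over its genes, glycinin therefore had a log2 ratio of only -0.25 (-0.26 to -0.25), and β-conglycinin one of -2.24 (-2.25 to -2.23). These lay much closer together with single-place reads, at -0.82 and -1.09, and with duplicates counted once, at -0.21 and -0.55. Of the 50 glycinin reference sequences with at least 20 reads, 26 were lower by the size rule and 15 higher. Of the 59 β-conglycinin sequences, 51 were lower and 7 higher. These families share long stretches of sequence, so reads can be assigned to the wrong copy, and values of single copies are uncertain.

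**Figure D1:**
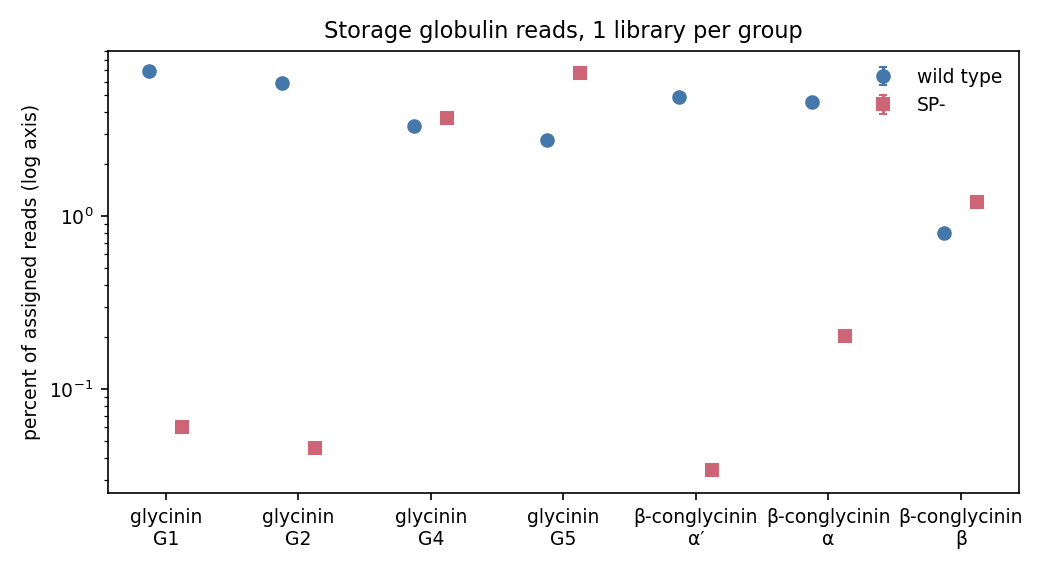
Percent of assigned reads on each storage globulin gene (log axis) in the wild-type library (circles) and the SP- library (squares), with exact 95% binomial intervals that are smaller than the symbols and 1 library per group. Glycinin G1, G2 and the α′ and α subunits lie far lower in SP- (G1 at 0.0600% against 6.90%), while G5 lies at 6.70% against 2.75%; G4, at 3.70% against 3.30%, has a log2 ratio that turns from 0.75 to -0.15 with scaling to the total outside storage globulins.

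Across all 37924 reference sequences with at least 20 reads, 1544 were higher and 929 lower in SP- by the size rule, which asks that the whole interval lie beyond 2-fold. Higher sequences made up 62.4% of these calls. That balance depended on the scaling and on how reads were counted. With duplicates counted once 268 were higher and 396 lower, and with single-place reads 804 and 572. With the total of assigned reads, which shifted every log2 ratio by -0.59, 707 were higher and 3282 lower, or 17.7% higher. With the total outside storage globulins, which still includes rRNA and shifted every log2 ratio by -0.90, the counts were 470 and 6124, or 7.13% higher. With the total outside rRNA, a shift of -0.22 chosen after the data were seen, they were 1137 and 1451, or 43.9% higher.

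Among other abundant seed proteins, 48 of 132 sequences were higher and 2 lower. The list median of 0.80 lay above all 10000 random lists of matched abundance, whose members were drawn independently. It turned to -0.11 with scaling to the total outside storage globulins, and was 0.57 with the total outside rRNA. Basic 7S globulin, a cysteine-rich extracellular seed protein, stood out at 38.6-fold higher (37.3 to 39.9), from 3612 reads in the wild type to 82704. Soybean agglutinin, the seed lectin, was 3.59-fold higher (3.56 to 3.63). The log2 ratio of the small sulphur-rich protein leginsulin was 1.68, and that of 2S albumin, a methionine-rich storage protein, 1.23. With scaling to the total outside storage globulins all 3 fell within 2-fold, agglutinin to 0.94, leginsulin to 0.78 and 2S albumin to 0.33. The vacuolar protein P34 had 546456 reads in the wild type and 626037 in SP-, a log2 ratio of 0.95. Kunitz trypsin inhibitor had a log2 ratio of 0.88, which turned to -0.03 with scaling to the total outside storage globulins. The Bowman-Birk inhibitor of trypsin and chymotrypsin had a log2 ratio of -0.87, within 2-fold, but -1.47 with scaling to the total of assigned reads and -1.78 with the total outside storage globulins. Both lower sequences of the list matched it, and 0 of its 9 sequences lay above 0.

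Of 11 oil body sequences, 7 were higher and none of them lower (median 1.10, or 0.51 with scaling to the total; percentile 98.0 among random lists). The list stood mainly for 1 protein: 10 of its sequences matched the 24 kDa oleosin, 6 of them higher. The other matched caleosin, with 16 reads in the wild type and 140 in SP-. The 24 kDa oleosin, a coat protein of oil bodies, had a log2 ratio of 0.85, which turned to -0.06 with scaling to the total outside storage globulins. Of 39 sequences of fatty acid and oil synthesis, 12 were lower and 0 higher, and the median of -0.99 lay below all random lists. Of the 12 lower sequences, 11 matched FAD2, the desaturase that converts oleate to linoleate. FAD2 had 27108 reads in the wild type and 1427 in SP-, 11.3-fold lower (10.7 to 11.9), and its log2 ratio was -1.76 with duplicates counted once. Stearoyl-ACP desaturase had a log2 ratio of -0.64 and the linoleate desaturase FAD3 one of -0.77, or -1.23 and -1.36 with scaling to the total. DGAT1, which makes triacylglycerol, had one of 0.43 (0.15 to 0.71), which turned to -0.16 with scaling to the total.

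Defence-related sequences formed the list with the highest median, 4.45, with 9 of 10 members higher. All 9 matched PR-10, a small intracellular pathogenesis-related protein, which was 19.99-fold higher in sum (17.8 to 22.5). Heat shock proteins as a list lay within the range of random lists (median -0.18, percentile 9.28), with 5 of 59 members higher. Within it, class I small heat shock proteins, which hold unfolding proteins in solution, were 8.30-fold higher (7.88 to 8.75), carried by TC284123 (log2 5.13) and TC283194 (3.74). Cytosolic HSP70, a general chaperone, had a log2 ratio of 0.34, which turned to -0.25 with scaling to the total of assigned reads, and HSP90 one of -0.30, or -1.20 with scaling to the total outside storage globulins. Sequences for folding in the endoplasmic reticulum had a median of -0.35 (percentile 0.0300), with 3 of 71 members higher and 4 lower. The chaperone BiP had a log2 ratio of 0.37, which turned to -0.22 with scaling to the total. Protein disulfide isomerase had one of -0.90 and calreticulin, a calcium-binding chaperone, one of -0.50; with scaling to the total both passed 2-fold, at -1.49 and -1.09. The rRNA share, 12.5% of reads in the wild type and 32.3% in SP-, differed alongside all of these groups.

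Amino acid metabolism had 24 of 64 sequences higher and 1 lower (median 0.70, above all random lists), and turned to -0.20 with scaling to the total outside storage globulins. Of the 24, 20 matched S-adenosylmethionine synthetase, which makes the methyl donor of the cell and had a log2 ratio of 1.83, or 0.92 with scaling to the total outside storage globulins. Asparaginase had a log2 ratio of 1.13, asparagine synthetase -0.52 and methionine synthase 0.22; with scaling to the total these were 0.53, -1.11 and -0.37. The list of proteasome and ubiquitin conjugation had 17 of 52 sequences higher (median 0.94, above all random lists). Its median was 0.35 with scaling to the total and 0.04 with the total outside storage globulins. All 17 matched ubiquitin-conjugating enzyme E2. With single-place reads, 2 of the 4 E2 sequences with the most reads turned, TC300143 from 1.62 to -0.17 and TC314443 from 1.71 to -2.74. The proteasome subunit searched for had a log2 ratio of -0.08. Among vacuolar sequences, 3 of 28 were higher and 1 lower (median 0.45, percentile 96.8), and the median turned to -0.14 with scaling to the total. All 4 of those matched the seed tonoplast aquaporin α-TIP, whose sum had a log2 ratio of 1.56, or 0.97 with scaling to the total and 0.66 with the total outside storage globulins.

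Photosynthesis sequences went both ways: 16 of 187 were higher and 19 lower, with a median of -0.41 below all random lists. Chlorophyll a/b-binding proteins had 8 of 135 sequences higher and 19 lower, with a sum at -0.25, or -1.16 with scaling to the total outside storage globulins. The Rubisco small subunit had 8 of 49 sequences higher and 0 lower, with a sum at 1.27, or 0.68 with scaling to the total and 0.36 with the total outside storage globulins. Sucrose synthase, which opens sucrose for use in the seed, had a log2 ratio of -0.75 and stood for the list of starch, sucrose and raffinose metabolism (0 of 24 beyond 2-fold, median -0.58, percentile 0.130); with scaling to the total its ratio was -1.34 and the list median -1.17, both beyond 2-fold. Cytosolic ribosomal proteins had a median of -0.29 (percentile 0.240, 3 of 76 lower), and cell division sequences, mainly histones, one of -0.44, below the central 95% of random lists (1 of 154 higher and 3 lower).

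Other lists lay within the range of random lists. Seed maturation regulators, among them ABI3 and LEC1, had a median of -0.19 (percentile 25.2), with 0 of 20 members beyond 2-fold. The 5 argonaute 1 sequences of the RNA silencing list had a median of 0.78 (percentile 97.1), which turned to -0.13 with scaling to the total outside storage globulins. Late embryogenesis abundant proteins, which accumulate as seeds dry, had a median of 1.13 (percentile 95.7), or 0.54 with scaling to the total, with 1 of 4 members higher. This list held no dehydrin, as the dehydrin of the panel reached only 35.1% identity. Reference genes had a median of -0.01 (percentile 39.6), which turned to 0.05 with the trimmed mean of log ratios, and 23 of 348 sequences were higher and 15 lower. Elongation factor 1-alpha had a log2 ratio of 0.93, and glyceraldehyde-3-phosphate dehydrogenase one of -0.90, or -1.50 with scaling to the total, with TC295505 at -4.09 (-4.25 to -3.94). Flavonoid synthesis and seed coat markers had no measured member.

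**Figure D2:**
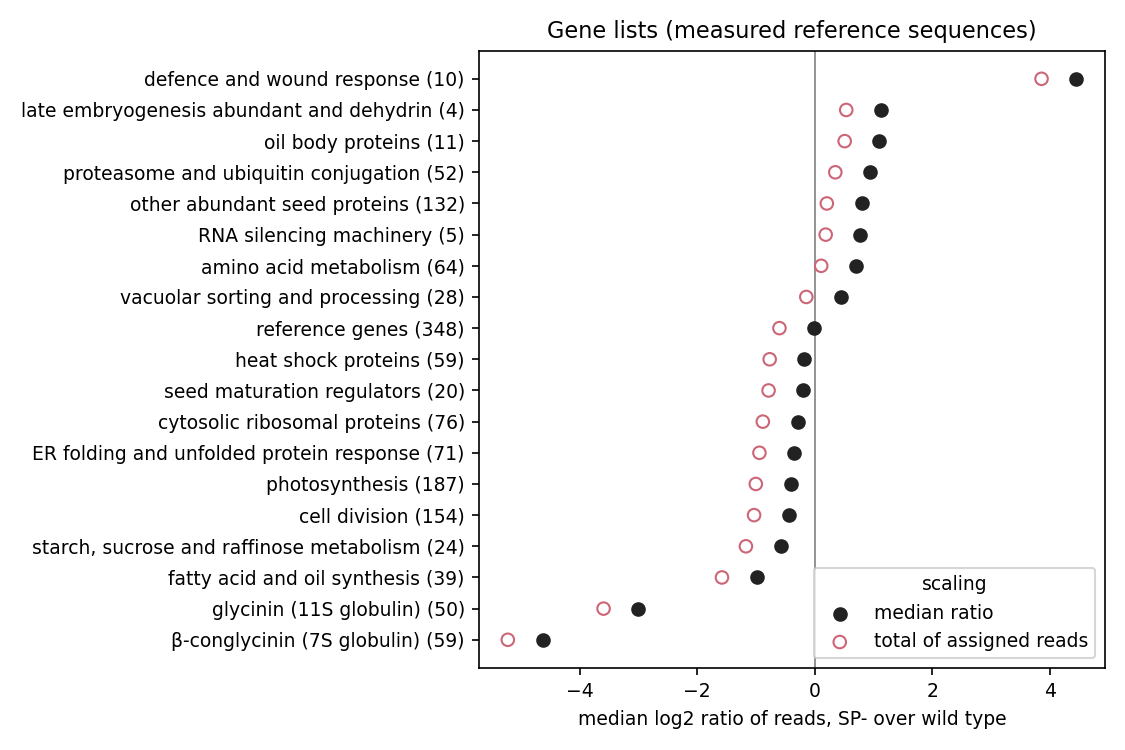
Median log2 ratio of reads, SP- over wild type, for each gene list with the number of measured reference sequences in brackets, from 1 library per group. Filled points use the median-ratio scaling and open points the total of assigned reads, which moves every median by -0.59 and takes the vacuolar list from 0.45 to -0.14; defence lies highest at 4.45 and β-conglycinin lowest at -4.63.

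The sequences with the most extreme ratios outside the storage globulins repeated some of these groups. Among the 10 highest were 3 sequences of basic 7S globulin (TC277885 at log2 5.42) and 1 of PR-10. Among the 10 lowest were 2 sequences of FAD2 (TC307991 at -4.62). The remaining sequences had no match to the protein panel used for naming. TC338655 went from 15330 reads to 118, and it shared a run of 68 identical bases with glycinin G1. AW395688 went from 408 reads to 5, and shared a run of 32 bases with glycinin G2. TC296725 went from 536 reads to 4, a log2 ratio of -6.14 (-8.19 to -4.95). The most abundant sequences of SP- that were not storage globulins were rRNA, P34 and seed lipoxygenase, an enzyme that oxidises polyunsaturated fatty acids (TC277842 at log2 0.96).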

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

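No paired analysis was possible because each group had 1 library. The settings that leave out rRNA, leave out storage globulins and rRNA, or use names by protein match alone were chosen after the results were seen. The cause of the shifts below was not tested, except where the setting itself moves every ratio alike. The storage globulin share was 29.1% in the wild type and 11.9% in SP-. It was 25.4% and 11.05% with single-place reads, 29.6% and 12.1% without mismatches, 28.9% and 11.9005% without the first run, and 29.2% and 11.976% without the second. It was 33.2% and 17.6% without rRNA in the total, and 28.7% in the wild type with names by protein match alone. Counting duplicates once gave 2.25% and 1.80%, as it limits each start position to 1 read per strand. The log2 ratios of glycinin (-0.25) and β-conglycinin (-2.24) stayed below 0 in every setting run. They were -0.84 and -2.83 with the total of assigned reads, -1.16 and -3.14 with the total outside storage globulins, -0.19 and -2.18 with the trimmed mean of log ratios, and -0.47 and -2.46 with the total outside rRNA. They were -0.82 and -1.09 with single-place reads, -0.21 and -0.55 with duplicates counted once, and -0.28 and -2.27 without mismatches. They were -0.34 and -2.33 without the first run, -0.36 and -2.35 without the second, and -0.23 and -2.23 with names by protein match alone. The counts of 1544 higher and 929 lower sequences became 707 and 3282 with the total of assigned reads, and 470 and 6124 with the total outside storage globulins. They became 804 and 572 with single-place reads, 268 and 396 with duplicates counted once, 999 and 608 without the second run, 2838 and 2236 beyond 1.5-fold, and 404 and 191 beyond 4-fold. At least 100 reads left 468 lower, and the total outside rRNA gave 1451 lower. Of the 1544 higher sequences 728 were also higher with single-place reads, and of the 929 lower ones 470 were also lower. The number of lists outside the central 95% of random lists, 13 of 19, ranged from 10 to 14. Members that are parts or copies of 1 gene can raise this number. The glycinin list median reversed to 0.49 with names by protein match alone, which leaves out 3 sequences each of G1 and G2 and 1 of G4. The medians of other abundant seed proteins and amino acid metabolism reversed to -0.11 and -0.20 with the total outside storage globulins. That total still includes rRNA, and with the total outside rRNA these medians were 0.57 and 0.48. Of 1799 alternative values of named sequences, 7 reversed a called direction. With single-place reads these were E2 sequences at -0.17 and -2.74, and sequences of the α subunit at 0.34, G5 at -1.81 and G1 at 3.04. With duplicates counted once, they were the β subunit sequence AW317985 at 0.46 and a protein disulfide isomerase sequence at 0.30. Depth limits the low sequences: those of under 20 reads were not called.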

Other observations

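The motif families, the tests of scaling for FAD2 and for the stress-related families with their bound and division by family, the tests without the top sequences and of seed stage, and the random draws of FAD2 reads, were chosen after the results were seen. Several of the most extreme sequences without a panel match carried protein motifs of known families. Dehydrins, hydrophilic proteins of drying seeds, had 3 measured sequences, all higher in SP- and 39.0-fold so in sum (32.2 to 47.7). TC285095, with the alpha-crystallin domain of small heat shock proteins, went from 1013 reads to 23732, a log2 ratio of 5.30. Type 4 metallothioneins, metal-binding proteins of seeds, had 5 of 6 sequences higher and a sum at 2.24. Type 2 metallothionein, which was named by the panel and belonged to no list, had 32 of 46 higher and a sum at 1.90. Sequences like glucose and ribitol dehydrogenase had 5 of 5 higher and a sum at 2.17, with TC277990 at 5.44, while their median of 1.43 lay within random lists (percentile 93.6). The 6 oleosin sequences found by motif had 0 higher and a sum at 0.02, which turned to -0.57 with scaling to the total. At the other end, a dirigent protein sequence, of a family that guides phenolic coupling, had 1008 reads in the wild type and 3 in SP- (log2 -7.42, -9.92 to -6.09). A sequence of the ACC oxidase type went from 543 reads to 2 (-10.38 to -5.47), and 1 with a hypoxia-induced domain from 431 to 3 (-8.70 to -4.86). The alcohol dehydrogenase sequence TC284422 went from 4886 reads to 58, while 16 of the 19 sequences of that family were not called.

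FAD2 reads were 11.3-fold lower in SP- although FAD2 is no storage protein. The log2 ratio nearest 0 over 4 scalings and 2 runs was -3.43, which argued against scaling as the whole cause. The other scalings moved every ratio alike, by -0.90 to 0.06, so this outcome followed from the size of the ratio. Silencing through sequence shared with the storage globulins had called for a common run of 21 bases, and the longest was 17. A candidate explanation is a FAD2 fragment transcribed from the transgene: in SP- 43.1% of the reads of TC277912 lay in the 300 bases where SP- reads were densest, near its 3' end, against 22.5% in the wild type, a ratio of 1.91. As choosing the densest bases raises this ratio, 2000 random draws of wild-type reads had theirs chosen the same way and gave at most 1.34, but they cover counting error only. Reads inside these bases were also lower (log2 -2.04, against -3.42 outside), and fragments left after cleavage of the transcript, or reads from a related copy, may give the same picture, and the transgene sequence was not analysed here.

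The rRNA share of reads was 12.5% in the wild type and 32.3% in SP-. The log2 ratio of rRNA was 1.96, and 0.73 with duplicates counted once, which limits each start position to 1 read per strand. A fault of 1 run was argued against, as the smaller ratio of shares by run was 2.52. Loss of 5' ends was also argued against: over 104 full-length sequences, the mean read position moved by -0.00482 of the length towards the 3' end (-0.0130 to 0.00237), where a move above 0.05 had been set as the sign of it. Less complete poly(A) selection in 1 library could shift rRNA sequences alike. Their log2 ratios had an interquartile range of 1.27 (0.940 to 1.70) against 1.06 for other sequences. A range at least that of other sequences had been set as the sign against this cause, and the value met it. The interval, which was not part of the rule as set, reached below 1.06, so the question was left undecided. Library preparation and line cannot be told apart with 1 library each, and a biological difference in rRNA stays untested.

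Dehydrins, metallothioneins and small heat shock proteins were picked because some of their sequences were extreme, so their values describe these families and no wider theme. Sums here take only sequences with at least 20 reads. Scaling as the whole cause was argued against where the smallest log2 ratio over 4 scalings and 2 runs stayed beyond 2-fold. It did in dehydrins (4.38), type 4 metallothioneins (1.34), class I small heat shock proteins (2.18, from 3.09) and TC285095 (4.40). In all of these the outcome followed from the size of the ratio, as a scaling moves every ratio alike. The smallest values came with the total outside storage globulins, which moved every log2 ratio by -0.90. Scaling stays open for type 2 metallothionein, whose 1.90 (1.86 to 1.94) fell to 0.995 (0.957 to 1.034) with the total outside storage globulins, which ended its call. A few sequences did carry the small heat shock proteins: without the 3 of 9 sequences with the most SP- reads, their sum moved from 4.35 to 0.23. These 3 held 31290 of the 31981 SP- reads, and picking by SP- reads favours such a fall. The sum of 52 metallothionein sequences, type 2 and type 4 together, stayed at 2.06 without the top 3, which held 29776 of 58126 SP- reads. As 3 of 52 is a smaller part of a family than 3 of 9, the 2 results cannot be compared directly. The 3 dehydrin sequences were too few to ask. Seeds of a later stage in the SP- library may be a source. The lists had the signs it calls for, but these were known when the test was set. Late embryogenesis abundant proteins were at 1.13 (percentile 95.7, 1 of 4 members higher), fatty acid and oil synthesis at -0.99 (below all random lists) and seed maturation regulators at -0.19 (percentile 25.2). The late embryogenesis abundant list did not hold the dehydrins found by motif. Of the 12 lower sequences of fatty acid and oil synthesis, 11 matched FAD2. Among the regulators, ABI3 and LEC1 sequences had medians of 0.47 and 0.34, and FUS3 and WRI1 sequences -0.72 and -0.55. The summed reads of LEC1 went the other way from its median, at -0.36 (-0.48 to -0.25). Those of ABI3, FUS3 and WRI1 kept their signs, at 0.495, -0.81 and -0.39. As the late embryogenesis abundant and regulator lists lay within random lists and each group is 1 library, stage and line cannot be told apart. An effect of the line itself stays open as untested.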
